A study of Mus musculus with 3 samples.

How the data were processed

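The data are single-cell RNA sequencing counts of macrophages sorted from mouse quadriceps 1 week after volumetric muscle loss. There is 1 library for each of 3 treatments: urinary bladder matrix (UBM), saline and polycaprolactone (PCL). The deposited table holds raw UMI counts for 13242 genes in 4374 cells, per the file headers and the values, which are whole numbers up to 1880. A second deposited table gives each cell's condition and the authors' cluster. Every cell of one table was found in the other. The condition names for saline and PCL in that table were matched to the labels by meaning (phosphate-buffered saline, and synthetic), and that for UBM likewise as extracellular matrix.

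Per the submitters' design text, libraries were made with a 10x droplet kit, aligned and counted with Cell Ranger, and the conditions were pooled, normalized and scaled, followed by principal components and clustering of a shared nearest neighbour graph with the Louvain method in Seurat. The processing notes name Seurat version 2, give no version of Cell Ranger and list genome build hg38, although the gene symbols are those of mouse. Of the symbols, 12831 (96.9%) were found in a mouse gene annotation on GRCm38, which was used for positions. Filters on cells and genes are not given in the sources used here. The meaning of the letters in the authors' cluster names is not given either.

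These choices were made before the data were examined: the comparisons, the rule for named genes, the gene lists and the lack of any test. With 1 library per condition no test, p-value or standard error was computed, since cells of 1 library are not replicates. UMIs were summed per gene over the cells of a library and divided by the library's total and multiplied by 1000000 to give counts per 1000000 UMIs (CPM). Each CPM has an exact Poisson 95% interval and each ratio an exact conditional binomial 95% interval. Shares of cells have exact Clopper-Pearson 95% intervals. These cover counting error only, and not the differences between cells, mice or libraries. A gene at 0 was given a floor of 3 counts per library, and a share of 0 cells in a cluster or library is given the limit of 3 cells of the total. Depths ranged from 1888343 UMIs in 341 saline cells to 14586276 UMIs in 2280 UBM cells.

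Named genes were, for each pair of conditions, the 10 with the highest and the 10 with the lowest log2 ratio after adding 10 CPM, among genes with at least 50 CPM in the higher library, without the 13 mitochondrial and 98 ribosomal protein genes. For each gene list the 2 highest and the 2 lowest members were eligible, and each cluster's 5 defining genes were those with the highest ratio to all other cells, among genes with a ratio above 1 in every library with at least 20 cells in it. Il1f9, Cd9, Il1b, Il23a, Il17ra, Il17rc, Il1rl2, Tgfb1, Mrc1, Mgl2, Arg1 and Adgre1 were named at any value. Genes at least 2-fold higher or lower after adding 10 CPM, over all cells or within clusters, were counted as a rule of size, which is not a test. Folds given for single genes are ratios of CPM with nothing added. Log2 ratios of genes have 10 CPM added unless stated, so folds and log2 ratios are not on 1 scale. Further markers named for a cluster come from its 10 genes with the highest ratio, and a cluster was taken as another cell type where at least 3 of these were markers of that type. Monocytes, the precursors of macrophages, were not counted as another type, so F1, with 3 monocyte markers, was kept, and F2 and R3 were set apart by this rule. The rule did not weigh macrophage markers, and R3 had the highest Lyz2, C1qb, C1qc and Cd68 of all clusters, so R3 may still hold macrophages. Single-cell contributions and the levels of list members in clusters were given for genes chosen after their values were seen.

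There were 17 lists of programs and 17 lists of cell-type markers, written from textbook knowledge. Members needed 10 CPM in at least 1 of the libraries compared. Members at least 1.5-fold higher or lower, with nothing added to the CPM, were counted. A list's median log2 ratio, with 10 CPM added, was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. In the glycolysis and hypoxia list for UBM against saline and in the neutrophil list for PCL against saline, 1 member was at 0 in saline, and the medians with that member at its bound were also 1.53 and 1.36. Comparisons within clusters used clusters with at least 50 cells in both libraries. Shares of cells with a UMI were also computed after each cell was thinned to 2500 UMIs, which left out 395 cells with fewer.

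Alternatives changed 1 choice at a time: scaling by trimmed mean of M values (edgeR 4.0.16 in R 4.3.3), by the median of ratios, or by the total without ribosomal protein genes and Malat1; each cell counted alike; equal weight for the clusters with at least 50 cells in every library; a pseudocount of 1 CPM; no minimum CPM; and new clusterings. Cells were also left out by Scrublet calls (run per library with an expected 0.8% of doublets per 1000 cells, 17 cells called), by the highest 5% of Scrublet scores, by over 10% mitochondrial UMIs, by having UMIs among the lowest 10%, or by cluster. The new clusterings used 2000 variable genes, 20 components, 20 neighbours and the Leiden method at a resolution of 0.8. They gave 12 clusters, and 11 without the 67 named and cluster-defining genes, with adjusted Rand indices of 0.671 and 0.696 to the authors' clusters. New clusters were matched to the authors' by largest overlap.

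The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9. The intervals and the placement of lists were tested on simulated counts with 200 changed genes. Each gene's counts were drawn independently from a Poisson distribution at the rate pooled over the libraries compared. Such counts hold no spread between cells and no genes that vary together. The values that follow therefore check the calculation, and not how the intervals or placements hold for real cells. Over the fold sizes, 94.0 to 98.0% of the intervals for UBM against saline (2357 genes), 94.0 to 96.0% for PCL against saline (2579 genes) and 94.0 to 98.0% for PCL against UBM (2446 genes) held the true ratio. Of 200 unchanged lists, 6.50%, 4.00% and 4.50% lay outside the central 95% of random lists, and all 50 raised lists lay above. Doublet calls by Scrublet on sorted cells of 1 lineage find few doublets of like cells, and mitochondrial and depth filters were tried only as alternatives.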

Results

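Single-cell RNA sequencing was carried out on macrophages sorted from mouse quadriceps 1 week after volumetric muscle loss, a surgical injury that removes a piece of muscle. The wound received urinary bladder matrix (UBM, a scaffold of decellularised extracellular matrix), saline, or polycaprolactone (PCL, a synthetic polyester), with 1 library for each condition. The title of the series concerns macrophages that produce interleukin-36 gamma and fibrosis mediated by interleukin-17. The UBM library held 2280 cells and 14586276 unique molecular identifiers (UMIs), with a median of 5477 UMIs and 1746 genes per cell. The saline library held 341 cells and 1888343 UMIs, with a median of 4594 UMIs and 1649 genes per cell. The PCL library held 1753 cells and 11006118 UMIs, with a median of 5662 UMIs and 1934 genes per cell. At these depths a count of 0 allows up to 0.206 counts per 1000000 UMIs (CPM) in the UBM library, 1.59 CPM in the saline library and 0.273 CPM in the PCL library. Mice per library are not given in the sources used here, so no difference between conditions was tested. All intervals below are 95% intervals for counting error only.

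The first comparison concerned which macrophage populations each treatment held. FP1, a cluster marked by Spp1 (osteopontin), Pdpn (podoplanin) and Cav1 (caveolin), made up 59.1% of PCL cells (1036 of 1753, 56.8 to 61.4%), 21.1% of saline cells (72 of 341, 16.9 to 25.8%) and 4.34% of UBM cells (99 of 2280, 3.54 to 5.26%). F1, marked by the monocyte genes Ly6c2 and Plac8 and the interferon-induced genes Isg15 and Cxcl10, made up 25.96% of PCL, 18.8% of saline and 1.89% of UBM cells. Cxcl10 was seen in 93 and Plac8 in 419 of the 562 F1 cells. RP1, marked by the acute-phase gene Saa3, Arg1 (arginase) and the hypoxia-induced genes Bnip3 and Ero1l, made up 25.2% of UBM cells (23.4 to 27.0%), 3.81% of saline cells and 2.11% of PCL cells. RP2, marked by the lipid receptor Trem2 and the lipase Lpl, made up 28.1% of UBM, 11.1% of saline and 3.31% of PCL cells. RP2 was weakly set apart, as its top gene, Pmp22, was 2.55-fold above all other cells and Trem2 2.17-fold. R2, marked by the haemoglobin scavenger receptor Cd163 and the chemokines Ccl24 and Ccl8, held 254 UBM cells (11.1%) and no cell of the other conditions, which allows up to 0.880% of saline and 0.171% of PCL cells.

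RP3, marked by Lyve1 and the lectins Cd209d and Cd209f, made up 8.77% of UBM, 19.9% of saline and 5.25% of PCL cells. Cd209d was seen in 67, Cd209f in 58 and Lyve1 in 174 of the 360 RP3 cells. R1, marked by Cd209a and the antigen-presentation gene H2-DMb2, made up 12.7% of UBM, 13.5% of saline and 0.799% of PCL cells. Cd209a was seen in 34 and H2-DMb2 in 66 of the 349 R1 cells, while Tnip3, another of its defining genes, was seen in 285. R1 also had the highest level of the NK-cell gene Gzma (127 CPM), and whether it holds more than 1 cell type was not tested. R3, whose markers included 6 of the muscle-fibre genes such as Acta1 (skeletal actin) and Mylpf (a myosin light chain), made up 7.59% of UBM, 10.9% of saline and 0.913% of PCL cells. Acta1 was seen in 75 of the 226 R3 cells. R3 also had the highest levels of the macrophage markers Lyz2 (21296 CPM) and Cd68 (1042 CPM) of all clusters. F2, marked by the neutrophil genes S100a8, S100a9, Retnlg and Il1r2, held 8 UBM, 3 saline and 45 PCL cells (0.351%, 0.880% and 2.57%). These genes define the clusters, and several of them are also among the genes compared between conditions below.

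When the cells were clustered again without the named and cluster-defining genes, FP1 held 64.2% of PCL, 11.1% of saline and 3.29% of UBM cells, and F1 held 25.8%, 17.0% and 0.921%. With all genes in the new clustering F1 held 9.38% of saline cells. In the clustering without the named and cluster-defining genes, RP1 held 25.7% of UBM cells, no saline cell and 0.228% of PCL cells. In that same clustering RP2 held 25.5%, 1.17% and 0.399% of UBM, saline and PCL cells. R2 held 10.2% of UBM cells and again no saline or PCL cell, RP3 held 8.95%, 21.4% and 5.02%, and R1 held 17.9%, 21.4% and 1.03% of UBM, saline and PCL cells. R3 held 27.9% of saline cells against 7.28% of UBM and 0.799% of PCL cells, and F2 held 0.263% of UBM, no saline and 2.51% of PCL cells. Of the 13 saline cells in RP1, 11 had over 10% mitochondrial UMIs and the median was 42.7%, against 8 of 574 UBM cells, so that without such cells RP1 made up 0.629% of saline cells. A cluster that comes mostly from 1 library may be that library.

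**Figure D1:**
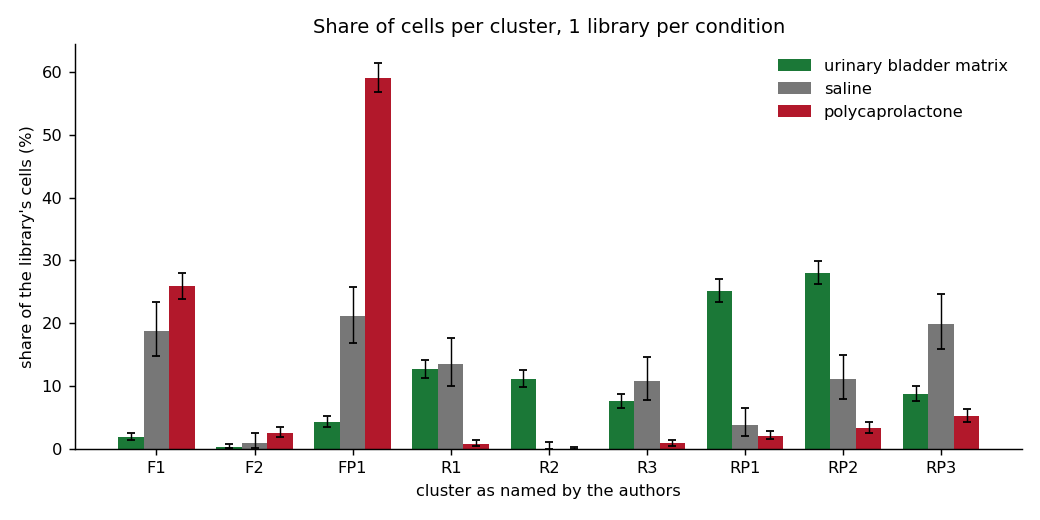
Bars give the share of each library's cells (%) in each of the authors' 9 clusters for urinary bladder matrix, saline and polycaprolactone, and lines give exact 95% binomial intervals. FP1 held 59.1% of polycaprolactone cells, and RP1 and RP2 held 25.2% and 28.1% of urinary bladder matrix cells.

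The second comparison set UBM against saline over all cells. Arg1, which breaks down arginine (chromosome 10, 24915221 to 24927484, minus strand, GRCm38), stood at 2973 CPM with UBM and 33.4 CPM with saline, 89.1-fold higher (69.6 to 116). Rnase2a, a ribonuclease of the eosinophil-associated family, had 4150 UMIs with UBM and none with saline, at least 179-fold higher against a floor of 3 counts. Saa3, an acute-phase protein, was 43.8-fold higher (29.8 to 67.0), and Chil3, a chitinase-like protein of alternatively activated macrophages, was 16.9-fold higher (12.9 to 22.5). The chemokine Ccl8 (chromosome 11, 82115185 to 82116799, plus strand) reached 12231 CPM with UBM and was 8.99-fold higher (8.65 to 9.35), and Ccl24, which attracts eosinophils, was 10.99-fold higher (9.59 to 12.7). Slc7a2, a transporter of cationic amino acids, was 20.8-fold higher (12.1 to 39.1), the glycolytic enzyme Pgk1 15.4-fold (9.86 to 25.7), Bnip3 9.71-fold (7.60 to 12.6) and Mmp12, the macrophage elastase, 7.74-fold (6.87 to 8.74). Of the 278 saline Mmp12 UMIs, 25.5% came from 1 cell.

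Among the genes lower with UBM, the fractalkine receptor Cx3cr1 stood at 7.88 CPM against 178 CPM with saline, 22.6-fold lower (18.2 to 28.1). Il1b, which encodes the inflammatory cytokine interleukin-1 beta, was 7.50-fold lower (6.98 to 8.06), the fungal receptor Clec4n 6.80-fold lower (6.05 to 7.65) and Ms4a4c 8.94-fold lower (7.38 to 10.8). S100a8, a neutrophil and monocyte protein (chromosome 3, 90668978 to 90670035, plus strand), was 12.3-fold lower (10.2 to 14.8), with 37.9% of its saline UMIs in 1 F2 cell. Its log2 ratio, with 10 CPM added, was −2.90 over all cells and −0.38 without F2. The other 5 of the 10 lowest were muscle-fibre genes, which also define cluster R3: Acta1 14.8-fold lower (12.1 to 18.2), Myl1 20.6-fold, Mylpf 13.04-fold, Tnnt3 22.7-fold and Tnnc2 14.8-fold. All 8 measured muscle-fibre markers were lower with UBM (list median log2 ratio −2.43). Among 2651 genes with at least 50 CPM in the higher library, 106 were at least 2-fold higher and 169 at least 2-fold lower with UBM, against 122 and 131 with trimmed-mean scaling and 118 and 134 with median-of-ratios scaling. The named 10 highest genes were higher in 10 of 10 cases within FP1 and in 9 of 10 within RP3, and the 10 lowest were lower in 9 and in 8 of 10, but by at least 2-fold in 7 and 5 of 10. The genes were chosen from these same counts, of which the clusters are parts, so some of this agreement follows from the choice.

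Genes of glycolysis and hypoxia stood higher together with UBM. Of 24 measured members, 22 were at least 1.5-fold higher and none was as much lower, with a median log2 ratio of 1.53 that lay above all 10000 random lists. Pgk1 and Bnip3 led this list, while hexokinase 2 (Hk2) differed by 1.07-fold (0.936 to 1.22). Of 18 alternative-activation genes, 12 were higher and 4 lower (median 0.75), and the lower ones included the chemokines Ccl17 (4.29-fold, 2.75 to 6.59) and Ccl22 (11.6-fold, 5.62 to 24.6). MHC class II presentation genes were lower in 10 of 10 (median −1.75 over all cells, −2.06 within FP1 and −0.34 within RP3), with H2-Ab1, a chain of the class II molecule, at 1424 CPM against 5815 CPM and the costimulatory Cd86 5.65-fold lower (4.81 to 6.64). Interferon-response genes were lower in 21 of 24 (median −1.10 over all cells, −0.21 within FP1 and −0.52 within RP3), with Ifit3 9.01-fold lower (6.74 to 12.1) and the chemokine Cxcl10 6.25-fold lower (4.81 to 8.09), while Ifi27l2a differed by 1.02-fold. The measured members of the IL-36 and IL-17 axis were lower in 7 of 10 (median −1.12), among them Nfkbiz, an inducible NF-kB cofactor, at 4.27-fold (3.94 to 4.63). Inflammatory cytokines and chemokines were lower in 10 and higher in 5 of 19 (median −0.61), with the neutrophil-attracting Cxcl1 3.34-fold higher (2.93 to 3.82). Monocyte markers were lower in 7 of 10 (median −0.94 over all cells, −0.04 within FP1 and 0.07 within RP3), and F1, the cluster with monocyte and interferon-induced markers, held 18.8% of saline and 1.89% of UBM cells. The median of alternative activation lay above all 10000 random lists, and those of the MHC class II, interferon, IL-36 and IL-17, inflammatory, handling-stress, monocyte and muscle-fibre lists lay below all of them. Cell-cycle genes had a median of −0.17 over all cells, 0.67 within FP1, 0.32 within RP3 and 0.62 with FP1 and RP3 weighted equally.

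The tissue-resident list had a median of 0.42 (0.52 within FP1, −0.36 within RP3 and −0.29 with FP1 and RP3 weighted equally), with 7 of 14 members higher and 2 lower, led by Ccl8 and by Pf4, platelet factor, at 4.18-fold (4.03 to 4.34). Lipid-handling genes of the Trem2 type had a median of 0.47, with Mmp12 and the protease Ctsk (9.74-fold, 6.22 to 16.2) higher and the lipid carrier Apoe 2.26-fold lower (2.24 to 2.29). Fibrosis and matrix genes had a median of 0.28, with 10 of 23 higher and 5 lower, among them the collagenase Mmp13 at 12.8-fold higher (7.13 to 25.7) and the urokinase gene Plau at 3.86-fold lower (2.84 to 5.20). Handling-stress genes, which respond to tissue dissociation, were lower with UBM in 11 of 21 (median −0.69), with Nr4a1 5.24-fold lower (4.73 to 5.80) and Jun 3.13-fold lower (2.93 to 3.35). The median of all genes moved by 0.13 on the log2 scale with trimmed-mean scaling, in the direction of higher values with UBM. Ribosomal protein genes took 19.6% of UMIs with UBM, 15.9% with saline and 12.9% with PCL.

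**Figure D2:**
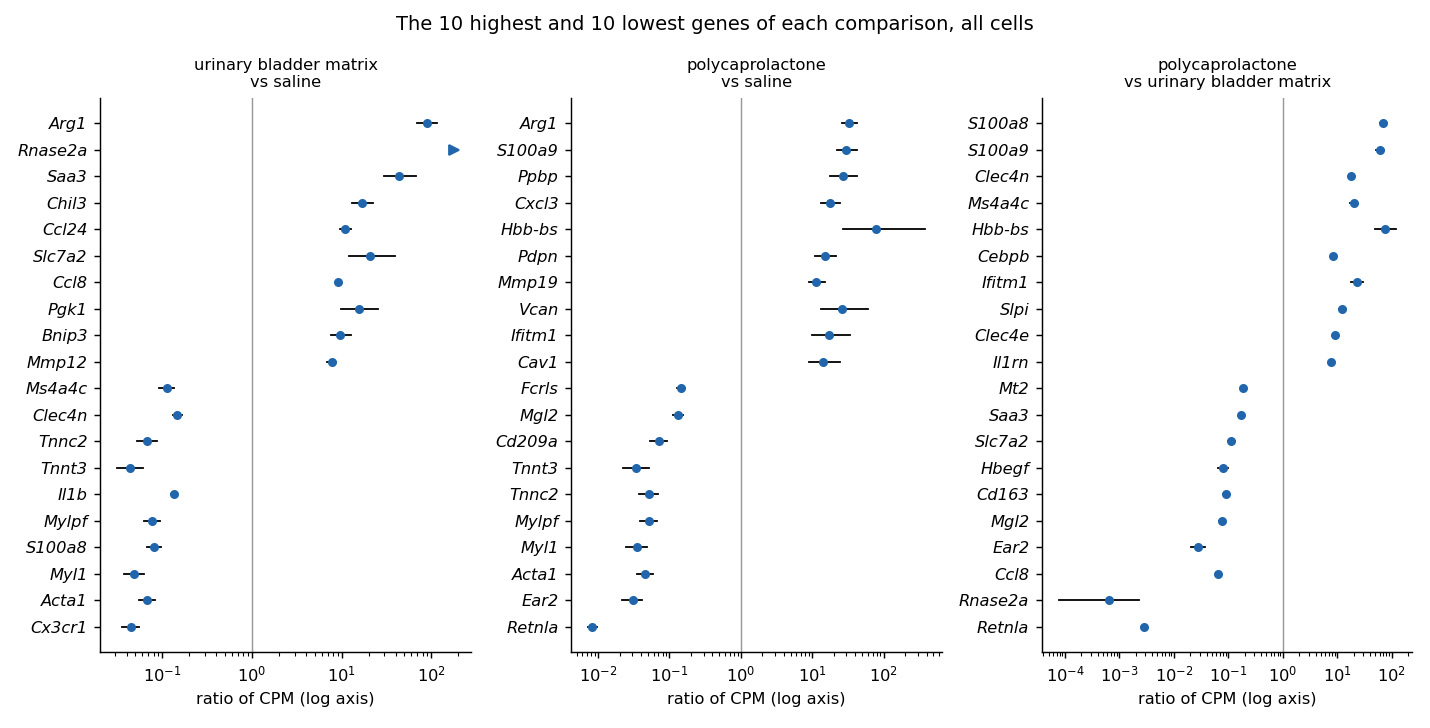
Points give the ratio of CPM on a log axis of the first to the second condition for the 10 highest and 10 lowest genes of each comparison over all cells, lines give 95% counting intervals, and the triangle is a lower bound for a gene at 0 with saline. Arg1 was 89.1-fold higher with urinary bladder matrix and 33.0-fold higher with polycaprolactone than with saline, and Retnla was 353-fold lower with polycaprolactone than with urinary bladder matrix.

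The third comparison set PCL against saline. Arg1 was 33.0-fold higher (25.8 to 43.0), at 1102 CPM against 33.4 CPM. S100a9, the partner of S100a8, was 30.0-fold higher (21.9 to 42.2), and the neutrophil-attracting chemokines Ppbp and Cxcl3 were 26.8-fold (17.7 to 42.8) and 17.7-fold higher (13.2 to 24.2). Genes that also define FP1 stood high: Pdpn 15.1-fold (11.03 to 21.3), the matrix protease Mmp19 11.5-fold (8.95 to 14.96) and Cav1 14.3-fold (8.93 to 24.7). The proteoglycan gene Vcan was 26.3-fold higher (13.3 to 61.1) and the interferon-induced Ifitm1 17.3-fold (9.88 to 33.6). S100a9 and Ifitm1 also define F2, the cluster with neutrophil markers. With 10 CPM added, their log2 ratios were 4.36 and 2.88 over all cells, and 3.21 and 1.98 without F2. Hbb-bs, a haemoglobin chain, had 1362 UMIs with PCL and 3 with saline (77.9-fold, 26.6 to 378), but 621 of them came from 1 cell, and 67.4 CPM remained without it.

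Retnla, a secreted protein of alternatively activated macrophages (chromosome 16, 48842551 to 48844461, plus strand), was the lowest gene with PCL, at 20.4 CPM against 2449 CPM with saline, 120-fold lower (105 to 138). Ear2, of the eosinophil-associated ribonucleases, was 32.9-fold lower (23.9 to 46.2), the lectins Cd209a and Mgl2 14.2-fold (10.7 to 18.9) and 7.62-fold lower (6.55 to 8.87), and the Fc receptor-like gene Fcrls 6.88-fold lower (6.06 to 7.82). In the PCL library 35.3% of Retnla and 30.7% of Mgl2 UMIs came from 1 cell each, both in cluster R1. Ear2 and Cd209a also define R1, which held 0.799% of PCL cells. With 10 CPM added, Cd209a had a log2 ratio of −2.63 over all cells and 0.15 with FP1 and RP3 weighted equally. The same 5 muscle-fibre genes completed the list, from 19.6-fold lower for Mylpf to 29.1-fold lower for Tnnt3, and all 8 measured muscle-fibre markers were lower (median −2.46). Among 2727 genes, 119 were at least 2-fold higher and 95 at least 2-fold lower with PCL, against 118 and 126 when the total leaves out ribosomal protein genes and Malat1. The 10 highest were higher in 10 of 10 cases within F1, FP1 and RP3, and the 10 lowest were lower in 10, 9 and 9 of 10, but by at least 2-fold in 6, 3 and 7 of 10. Here too the genes were chosen from the same counts, so some of this agreement follows from the choice.

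Glycolysis and hypoxia genes were higher with PCL in 21 of 23 (median 1.20), with Pgk1 at 11.5-fold (7.35 to 19.2). Fibrosis and matrix genes were higher in 13 and lower in 3 of 23 (median 0.97), with Spp1, a matrix-binding cytokine (chromosome 5, 104435118 to 104441050, plus strand), at 6296 CPM against 873 CPM, 7.21-fold higher (6.87 to 7.58). Of the saline Spp1 UMIs 41.0% came from 1 FP1 cell, and 519 CPM remained without it. Monocyte markers were higher in 9 of 11 (median 1.23) and neutrophil markers in 5 of 7 (median 1.36). Macrophage markers were lower in 5 of 9 (median −0.58), among them the complement gene C1qc at 2.52-fold (2.45 to 2.60). MHC class II genes were lower in 8 of 10 (median −1.20), with the peptide-loading gene H2-DMb1 3.14-fold lower (2.91 to 3.38). Tissue-resident genes were lower in 7 of 14 (median −0.65 over all cells, −0.41 within F1, −0.38 within RP3 and 0.34 within FP1), with the selenoprotein gene Sepp1 3.37-fold lower (3.26 to 3.48) and Pf4 3.75-fold higher (3.61 to 3.90). Alternative-activation genes went both ways, 8 higher and 6 lower of 17 (median 0.46), with Arg1 and Chil3 (7.02-fold, 5.36 to 9.38) at one end and Retnla and Ear2 at the other. Interferon-response genes had a median of 0.03 over all cells, with −0.38 within F1, 0.28 within FP1 and 0.51 within RP3. Inflammatory genes had one of −0.02, with −0.07 within F1, 0.33 within FP1 and 0.31 within RP3, and the IL-36 and IL-17 axis one of −0.16 (0.036 with FP1 and RP3 weighted equally). Cell-cycle genes were lower in 13 of 21 (median −0.58 over all cells, −1.13 within F1, −0.68 within FP1 and 0.46 within RP3), with the survivin gene Birc5 3.69-fold lower (2.70 to 5.02). Handling-stress genes were lower in 10 of 21 (median −0.46), with Egr1 4.62-fold lower (4.23 to 5.05). The glycolysis, fibrosis, monocyte and neutrophil medians lay above all 10000 random lists, and the MHC class II, tissue-resident, cell-cycle and handling-stress medians below all of them.

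The fourth comparison set the synthetic against the biological scaffold. With PCL, the neutrophil and monocyte genes S100a8 and S100a9 were 69.7-fold (60.5 to 80.8) and 59.9-fold higher (51.0 to 70.8). With 10 CPM added, their log2 ratios were 5.33 and 4.95 over all cells, and 3.80 and 3.43 without F2. The 45 PCL cells of F2 held 8002 of the 10204 S100a8 UMIs of the PCL library. In the PCL library S100a8 was seen in every cluster of at least 20 cells, from 137 to 320 CPM outside F2. Clec4n was 17.9-fold higher (16.5 to 19.5), Ms4a4c 19.98-fold (17.3 to 23.1), the transcription factor Cebpb 8.41-fold (8.14 to 8.69), the fungal and mycobacterial receptor Clec4e 9.13-fold (8.27 to 10.1) and Il1rn, the interleukin-1 receptor antagonist, 7.70-fold (7.12 to 8.34). Ifitm1 was 22.9-fold higher (18.0 to 29.6) and the protease inhibitor Slpi 12.5-fold (10.7 to 14.7). With 10 CPM added, the log2 ratio of Ifitm1 was 3.02 over all cells and 2.06 without F2. Hbb-bs, with the cell described above, was 75.2-fold higher (50.3 to 118). Retnla stood at 7187 CPM with UBM, 353-fold above PCL (310 to 404), and Rnase2a had 2 UMIs with PCL, 1566-fold lower (433 to 12933). Ccl8 was 15.6-fold lower (15.3 to 15.9), Ear2 35.9-fold (26.8 to 49.4), Mgl2 13.3-fold (11.8 to 14.9), Cd163 11.2-fold (10.0 to 12.6), the growth factor Hbegf 12.6-fold (10.3 to 15.7), Slc7a2 8.79-fold (7.55 to 10.3), Saa3 5.82-fold (5.47 to 6.20) and the metallothionein Mt2 5.29-fold (5.07 to 5.52). Arg1 was 2.70-fold lower with PCL than with UBM (2.64 to 2.75).

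Interferon-response genes were higher with PCL in 20 of 23 (median 1.01 over all cells, 0.32 within FP1, 0.59 within RP2 and 0.86 within RP3), with Ifit1 6.26-fold (5.36 to 7.34) and Ifi205 7.13-fold higher (5.92 to 8.65). Monocyte markers were higher in 11 of 11 (median 1.99), and MHC class II genes in 6 of 8 (median 0.78, or −0.38 with FP1 and RP3 weighted equally) with Cd86 3.94-fold higher (3.49 to 4.45). Members of the IL-36 and IL-17 axis were higher in 6 of 9 (median 0.99 over all cells, 1.42 within FP1, 0.96 within RP2 and 0.92 within RP3). The median over all cells was the value of Il1f9. With 10 CPM added, Il1f9 had a log2 ratio of 0.27 without F2. Outside F2 it stood at 2.23 CPM with PCL and 0.137 CPM with UBM, both far below the 10 CPM added. Inflammatory genes were higher in 8 and lower in 3 of 19 (median 0.42 over all cells, 0.76 within FP1, 0.90 within RP3 and −0.16 within RP2), with Il1b 6.52-fold higher (6.17 to 6.90) and Il6 2.71-fold lower (2.20 to 3.35). Alternative-activation genes were lower in 10 and higher in 3 of 17 (median −1.23 over all cells, −0.81 within FP1, −0.37 within RP2 and −0.61 within RP3). Their higher member Ccl22 had 108 of its 115 PCL UMIs in 1 cell. Tissue-resident genes were lower in 10 of 14 (median −1.03 over all cells, −0.17 within FP1, −0.26 within RP2, 0.10 within RP3 and 0.16 with equal weights). Fibrosis and matrix genes were higher in 12 and lower in 6 of 23 (median 0.32), with Mmp19 5.83-fold (5.43 to 6.26) and thrombospondin Thbs1 3.93-fold higher (3.77 to 4.09) and the growth factor Igf1 3.75-fold lower (3.57 to 3.94). Spp1 was 3.58-fold higher (3.53 to 3.64). Glycolysis and hypoxia genes had a median of −0.29, with 6 of 24 lower, among them adrenomedullin, Adm, at 15.8-fold (10.0 to 26.6). Cell-cycle genes were lower in 9 of 17 (median −0.34 over all cells, −1.32 within FP1, −0.43 within RP2 and 0.24 within RP3). The interferon, monocyte, and IL-36 and IL-17 medians lay above all 10000 random lists, and the alternative-activation and tissue-resident medians below all of them. Among 2670 genes, 162 were at least 2-fold higher and 78 at least 2-fold lower with PCL, so that 67.5% of them were higher. The counts were 150 and 128 when the total leaves out ribosomal protein genes and Malat1, and 131 and 109 (54.6% higher) with trimmed-mean scaling, which moved the median of all genes by −0.10 on the log2 scale. The 10 highest were higher in 10 of 10 cases within FP1, RP2 and RP3, and the 10 lowest were lower in 10, 10 and 9 of 10, by at least 2-fold in 10, 8 and 6 of 10. Some of this agreement again follows from choosing the genes from the same counts, and free RNA was not excluded for S100a8, S100a9 and Hbb-bs.

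**Figure D3:**
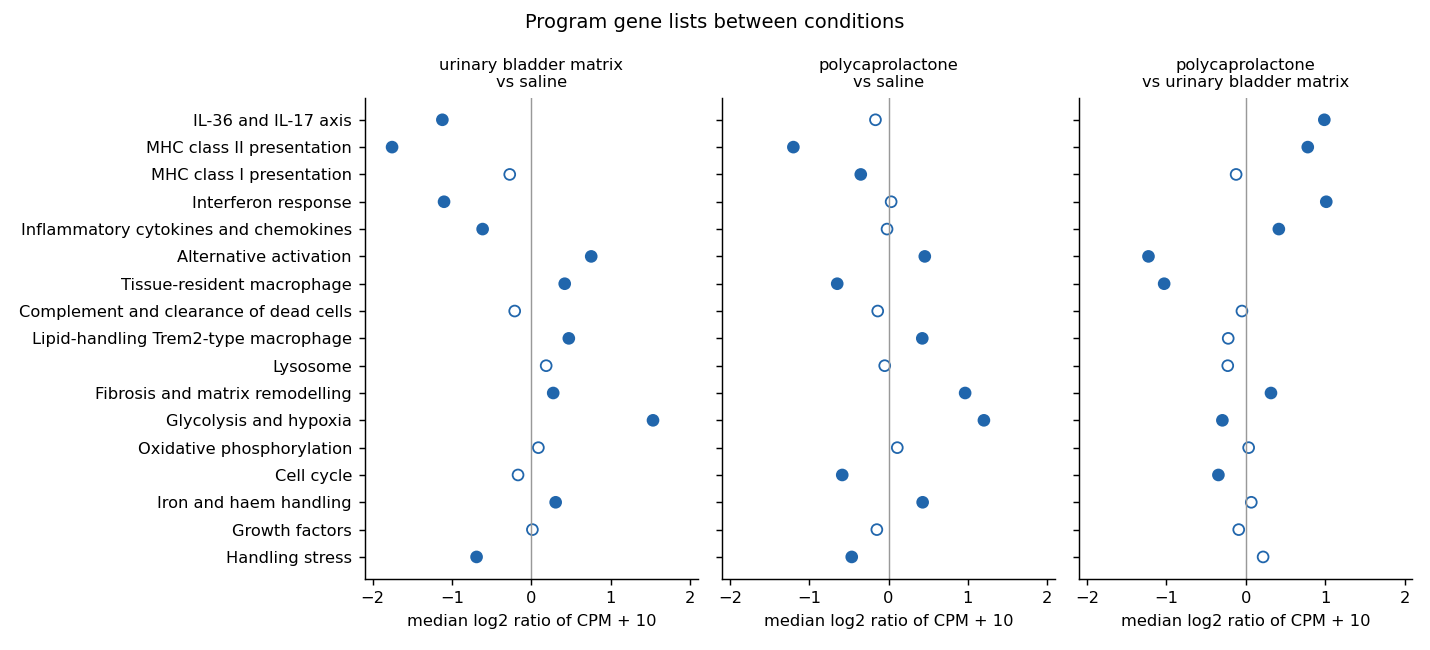
Points give the median log2 ratio of CPM, with 10 CPM added, over the measured members of 17 program lists in the 3 comparisons of conditions, filled where the median lies outside the central 95% of 10000 random lists matched on expression. Glycolysis and hypoxia genes had medians of 1.53 and 1.20 for the scaffolds against saline, and interferon-response genes had a median of 1.01 over all cells for polycaprolactone against urinary bladder matrix (0.32 within FP1).

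The fifth comparison asked whether cells of 1 cluster differed between conditions, apart from the mix of clusters. Within FP1, Retnla stood at 3779 CPM with UBM, 73.7 CPM with saline and 2.91 CPM with PCL, and Arg1 at 2949, 106 and 1512 CPM. Within RP3, Retnla stood at 23642, 5246 and 190 CPM, Ccl8 at 37982, 5893 and 9771 CPM, and Arg1 at 931, 3.72 and 72.4 CPM, the saline value being 1 UMI. Spp1 within RP3 was 40.2-fold higher with PCL than with saline (21.1 to 88.3) and 9.81-fold higher with UBM than with saline (5.10 to 21.7). Spp1 also defines FP1 (8320 CPM over all libraries), which held 59.1% of PCL cells. Whether free RNA from other clusters of a library contributes to Spp1, Arg1 or the other values here was not tested, apart from Retnla below. Il1b differed little between PCL and saline within F1 (1142 and 1204 CPM) and FP1 (434 and 418 CPM) but was 3.89-fold higher with PCL within RP3 (145 and 37.2 CPM, 2.01 to 8.40), and with FP1 and RP3 weighted equally its log2 ratio to saline was 0.33. Within FP1 UBM cells had 56.7 CPM of Il1b. Cx3cr1 within FP1 stood at 5.04 CPM with UBM against 264 CPM with saline. Glycolysis and hypoxia genes had medians of 1.20 in FP1 and 1.55 in RP3 for UBM against saline, and of 1.08 in F1, 0.93 in FP1 and 1.09 in RP3 for PCL against saline. For PCL against UBM, MHC class II genes had medians of 0.69 in FP1 and 0.90 in RP2 but −0.98 in RP3, a difference that was not tested. Handling-stress genes had medians of −1.25 in RP3 and −0.19 in FP1 for UBM against saline, and of −1.13 in RP3, −0.05 in FP1 and −0.51 in F1 for PCL against saline.

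The last comparison concerned the genes in the series' title and Cd9. Interleukin-36 gamma is listed under its older symbol Il1f9 (chromosome 2, 24186476 to 24193568, plus strand). Il1f9 UMIs were seen in 46 of 1753 PCL cells (2.62%, 1.93 to 3.48%), 3 of 341 saline cells (0.880%, 0.182 to 2.55%) and 4 of 2280 UBM cells (0.175%, 0.0478 to 0.449%). Cells thinned to 2500 UMIs gave 1.501%, 1.15% and 0.189%. Of all 127 Il1f9 UMIs, 79.5% lay in F2, the cluster marked by neutrophil genes, where 31 of 56 cells had one (55.4%, median 4346 UMIs per cell). None of the 349 cells of R1, 254 of R2 or 360 of RP3 had an Il1f9 UMI, at median depths of 7374, 8365 and 4346 UMIs, which allows up to 0.860%, 1.18% and 0.833% of cells with a UMI. Outside F2, Il1f9 was seen in 20 of 1708 PCL cells (1.17%, 0.717 to 1.80%), 2 of 2272 UBM cells and none of 338 saline cells, and in PCL cells the ratio of Il1f9 to S100a8 UMIs outside F2 was 0.948 times that inside it. Over all cells Il1f9 stood at 10.5 CPM with PCL, 3.32-fold above saline (1.48 to 9.22) and 30.7-fold above UBM (12.8 to 96.5). With 10 CPM added, its log2 ratio of PCL to UBM was 0.99, and 0.27 without F2. Outside F2 its levels, 2.23 CPM with PCL and 0.137 CPM with UBM, were far below the 10 CPM added.

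Cd9, a tetraspanin of the cell surface (chromosome 6, 125460266 to 125494791, minus strand), was seen in 77.9% of PCL cells (75.9 to 79.8%), 43.3% of UBM cells and 35.5% of saline cells, and in 62.1%, 30.3% and 30.2% after thinning. FP1 held Cd9 UMIs in 88.7% of cells at a median of 5538 UMIs, against 18.1% in R2, the cluster with the lowest level, at a median of 8365 UMIs. Cd9 was 3.23-fold higher with PCL than with saline (2.95 to 3.54), and 2.31-fold higher within FP1 (2.05 to 2.62). Il17ra, the receptor subunit for interleukin-17, stood at 37.3 CPM with PCL, 28.6 CPM with saline and 8.64 CPM with UBM, 4.31-fold lower with UBM than with PCL (3.52 to 5.31). Il1rl2, the interleukin-36 receptor, stood at 6.92 CPM with UBM, 4.77 CPM with saline and 2.63 CPM with PCL. Il23a, a subunit of interleukin-23, had 2, 0 and 3 UMIs with UBM, saline and PCL, which allows no fold, and Il17rc is not listed in the table. Tgfb1, the fibrosis cytokine, stood at 206, 241 and 214 CPM with UBM, saline and PCL. Mrc1, the mannose receptor, was 2.49-fold higher with UBM than with saline (2.33 to 2.67) and 0.909-fold with PCL (0.846 to 0.978), where the log2 ratio with FP1 and RP3 weighted equally was 0.13. Adgre1, the macrophage marker F4/80, stood at 430, 413 and 272 CPM.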

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

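All tests in this part were chosen after the results were seen, and for 2 of them, the search for neutrophil RNA in Il1f9 cells outside F2 and the depth of Il1f9 cells inside F2, the expected outcome was written before the value was known.

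Mt2, which encodes a metallothionein that binds zinc, went in opposite directions in different clusters between PCL and UBM. It was 1.63-fold higher with PCL within RP3 (1.45 to 1.83), 5.65-fold lower within FP1 (5.16 to 6.18) and 6.13-fold lower within RP2 (4.69 to 8.17). The difference between clusters was not tested, and each side rests on 1 library.

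The first pattern weighed is the Il1f9 signal in the PCL library, 92 UMIs inside F2 and 24 outside it. For the UMIs outside F2, doublets with an F2 cell cannot be told apart from other sources: 0 of 20 such cells (0%) held S100a8 and S100a9 at or above the 10th percentile of F2 cells, but these genes define F2, so the clustering would place such doublets inside it. Free RNA from F2-type cells could account for them only if S100a8 outside F2 is itself free RNA, which the third pattern below leaves open. The ratio of Il1f9 to S100a8 UMIs outside F2 was 0.948 times that inside it (0.578 to 1.499). S100a8 and S100a9 took a median of 0.0458% of UMIs in these 20 cells, against 0.0208% in the 1688 cells outside F2 without Il1f9. That difference was not tested. For the UMIs inside F2, neutrophils as the only source cannot be told apart from cells with macrophage RNA: 80.6% of the Il1f9 cells there (25 of 31, 62.5 to 92.5%) held macrophage marker RNA at or above the 5th percentile of FP1 cells, but so did 80.4% of all F2 cells, the markers include Lyz2, which neutrophils also express, and the level of free macrophage RNA is not known. A doublet of a neutrophil and a macrophage cannot be told apart from a single cell with both kinds of RNA. In the PCL library, the Il1f9 cells of F2 with macrophage marker RNA held a median of 6980 UMIs against 5530 in FP1 (1.26 times, in 20 cells). Il1f9 made by macrophages remains untested.

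The second pattern weighed is the higher Retnla and Ccl8 with UBM than with saline within clusters. The lowest lower bound of the ratio over both genes in FP1 and RP3 was 4.27, but the pattern was chosen by these ratios, so they test no explanation, and a different mix of cells inside each cluster was not tested. Free RNA in the UBM library is argued against as the whole cause for Retnla, since Retnla in FP1 was 7.15 times that in RP1 (6.71 to 7.62). Ccl8 was not put to this test, and it stood at 1613 CPM in FP1, between 468 CPM in R1 and 6056 CPM in RP1. The ratio of Ccl8 to Retnla ran from 0.0463 in R1 to 11.5 in RP1, a range of 248-fold. Free RNA alone would keep 1 ratio in every cluster, but this range does not show that FP1 cells make Ccl8. A batch of the library cannot be told apart from the treatment, since there is 1 library per condition, so the treatment may or may not be the cause.

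The third pattern weighed is S100a8 and Hbb-bs in every large cluster of the PCL library. Whether free RNA with the composition of F2 is the whole source of S100a8 cannot be told apart from a part made by the cells: the ratio of S100a8 to S100a9 was 1.20 times that in F2 in FP1 (1.13 to 1.27), and 2 of 4 clusters differed from F2 beyond counting error, but F1 (1.07) and RP3 (1.08) did not. The criterion for this test was changed after the ratios were seen, from a bound of 1.5, which FP1 does not reach, to the counting interval. Free RNA at a like level could account for Hbb-bs, a red-cell gene, as its UMIs per cell in FP1 were 1.05 times those in the other clusters (0.900 to 1.22) once the single cell with 621 UMIs was set aside, and 33.7 to 36.2% of the cells of F1, FP1, RP2 and RP3 held a UMI. No biological explanation was tested for this pattern.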

How the results depend on the processing

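The settings that leave out cells with high doublet scores, cells with a high mitochondrial share or cluster F2, the total without ribosomal protein genes and Malat1, the clustering without the named genes, the removal of a gene's top cell, and trimmed-mean scaling within clusters were chosen after seeing the data. No paired analysis was possible because each condition has 1 library, and no library can be left out.

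Over the settings tried, 724 of 1056 values of named log2 ratios stayed within their counting interval, 327 moved beyond it and 5 turned. A change of sign was counted as a turn only where the main interval left out 0, so moved values may include other changes of sign. Of 268 list medians 149 stayed, 110 moved and 9 turned, and of 162 cluster shares 133 stayed. Ratios within clusters were tried only with trimmed-mean scaling and without the highest doublet scores, and 421 of 450 stayed. Equal weight for the 2 clusters with at least 50 cells in each library, FP1 and RP3, changed most. It gave 53 genes lower for PCL against saline, and 101 higher and 47 lower for PCL against UBM. It turned Cd209a (log2 0.15), Il1b (0.33) and Mrc1 (0.13) for PCL against saline, and the list medians of MHC class I (0.024), tissue-resident (−0.29) and cell-cycle genes (0.62) for UBM against saline, IL-36 and IL-17 axis (0.036) and lysosome (0.0073) for PCL against saline, and MHC class II (−0.38), tissue-resident (0.16) and growth factors (0.028) for PCL against UBM. This setting drops 7 clusters by construction. Il1f9 for UBM against saline turned to log2 0.022 without F2 and R3 and to 0.020 without F2 alone, since few of its UMIs remain.

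With no minimum CPM more genes are counted by construction, 255 lower for UBM and 162 lower for PCL against saline, and the fibroblast median for PCL against saline turned to −0.094. With 1 CPM added in place of 10, 115 genes were counted higher and 205 lower for UBM against saline. The counts were 141 and 120 for PCL against saline, and 199 and 102 for PCL against UBM. The total without ribosomal protein genes and Malat1 gave 128 genes lower for PCL against UBM, and the cause was not tested. New clustering gave FP1 shares of 3.25% (UBM), 11.1% (saline) and 64.6% (PCL), and 3.29%, 11.1% and 64.2% without the named genes. RP1 then held 0% of saline cells in both, and 0.171% and 0.228% of PCL cells. The saline RP1 share was 1.15% without the lowest 10% of UMIs and 0.629% without cells of high mitochondrial share. Thinning lowers the counts of each cell but also leaves out cells with few UMIs, so a share can fall or rise. It gave 1.501% of PCL cells with Il1f9 and 30.3%, 30.2% and 62.1% of UBM, saline and PCL cells with Cd9. The Il1f9 share rose to 1.15% in saline and 0.189% in UBM cells. Without F2 the Il1f9 share was 0% in saline and 1.17% with PCL. Without the cell holding most UMIs of a gene, 68 of 88 named ratios stayed within their interval. Hbb-bs then had a log2 ratio of 2.81 against saline and 2.74 against UBM, where all cells gave 3.53 and 3.52. The 341 saline cells limit every comparison with saline.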

Other observations

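The single-cell contributions given here were looked up after the values were seen, and no other test was run for this part.

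Iron and haem genes had medians of 0.31 for UBM against saline (−0.10 within RP3) and 0.43 for PCL against saline, with different members in front. Haem oxygenase, Hmox1, was 6.13-fold higher with PCL than with saline (5.55 to 6.80), and the transferrin receptor Tfrc was 8.15-fold higher with UBM than with saline (4.64 to 15.8) and 5.75-fold lower with PCL than with UBM (4.66 to 7.17), with 5 of the 12 saline Tfrc UMIs in 1 cell. The list's median for PCL against UBM was 0.07. Growth factors had medians of 0.01, −0.15 and −0.09 for UBM against saline, PCL against saline and PCL against UBM. Hbegf was 6.77-fold (4.75 to 10.0) and Igf1 2.70-fold higher (2.46 to 2.96) with UBM than with saline, and Vegfa, which drives vessel growth, was 2.75-fold higher with PCL than with saline (2.21 to 3.47). Among genes for complement and the clearance of dead cells (medians −0.21, −0.14 and −0.05), the scavenger receptor Cd36 was 3.47-fold higher with UBM (3.11 to 3.88) and 4.16-fold higher with PCL (3.73 to 4.65) than with saline, and the receptor Axl was 7.51-fold lower with UBM than with saline (6.18 to 9.12). Lysosome genes had medians of 0.19, −0.05 and −0.23, and oxidative phosphorylation genes of 0.09, 0.11 and 0.04, inside the central 95% of random lists over all cells, with 0.41 and 0.49 for UBM against saline within RP3. MHC class I genes had medians of −0.27, −0.35 and −0.12, of which that for PCL against saline lay at percentile 0.11, with −0.52 within F1, −0.31 within FP1 and 0.15 within RP3. Lipid-handling genes of the Trem2 type had a median of 0.43 for PCL against saline over all cells (0.92 within F1, −0.04 within FP1 and 1.19 within RP3) and of −0.22 for PCL against UBM (−0.45 within FP1, 0.0018 within RP2 and 0.41 within RP3). Trem2 was 2.11-fold lower with PCL than with UBM (2.04 to 2.18).

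Lists of other cell types had few measured members. Fibroblast genes had medians of −0.30, 0.66 (−0.094 with no minimum CPM) and 0.59, with the collagen gene Col3a1 3.14-fold higher with PCL than with UBM (2.64 to 3.76). Neutrophil genes had a median of −0.11 over 4 members for UBM against saline and 1.498 over 7 for PCL against UBM. Macrophage genes had medians of −0.44 for UBM against saline (0.16 within RP3) and −0.37 for PCL against UBM (0.11 within FP1 and 0.16 within RP2). Conventional dendritic cell genes (Cd209a and Wdfy4) had medians of −1.09, −1.62 and −0.53. T cell genes had medians of −0.81, −0.71 and 0.43 over at most 3 members. For other types 1 member was measured: Tcf4 for plasmacytoid dendritic cells (−0.70, −0.64 and 0.06), Cd79b for B cells (−0.60 and −0.80 against saline), Des for satellite cells (−2.08 and −2.17 against saline) and Pecam1 for endothelium (0.77 for UBM against saline and −0.56 for PCL against UBM). Gzma, of NK cells, had 362 UMIs in 11 UBM cells, 129 of them in 1 R1 cell, and none with saline or PCL, at least 15.6-fold and 91.0-fold lower. Erythroid genes had a median of 2.29 for PCL against saline and, with Hba-a1 at its bound, 3.52 for PCL against UBM (2.43 otherwise), with 318 of the 485 PCL Hba-a1 UMIs in 1 cell. Mast cell, eosinophil, mural and Schwann lists had no measured member. Muscle-fibre genes had a median of −0.26 over 2 members for PCL against UBM. Handling-stress genes had a median of 0.22 for PCL against UBM.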
